A study of Arabidopsis thaliana with 18 samples.

How the data were processed

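Poly-A RNA of Arabidopsis hypocotyls was sequenced in 18 libraries, 3 for each of 6 groups, of 2 genotypes (WT and hy1) at 3 times (0 h in darkness, 12 h and 24 h in light). Per the labels RNA was extracted with TRIzol and libraries were made with a TruSeq kit. The values used were the deposited counts, whole-number read counts per gene that the authors made with featureCounts 2.0.3 per the file headers, on a TAIR10 annotation. Its options counted each mate of a pair as 1 read, ignored strand and left out reads that mapped to several places, so that 73.2% to 78.4% of counts from 1 to 10 were even. Per the labels STAR 2.7.8a, StringTie 2.1.3 and HTSeq were also used, with no role stated, and the count table itself names featureCounts. The deposited FPKM values, named so by the authors, were 10 times the FPKM computed from the deposited counts, exon lengths and library totals in all 408813 values compared, and were used in alternatives alone. A factor common to all values cancels in a fold change, though not in log2(FPKM + 1).

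Library totals ran from 38469946 to 59905064 counts. Of 32833 genes 6452 had no read, and 20955 passed edgeR's filterByExpr on the groups and were tested. A total of 32548 genes were found in the reference annotation by locus, 99.95% of them with the same start and end. TMM factors ran from 0.971 to 1.07, and the most abundant gene took 1.2% to 4.36% of a library. Plastid-encoded genes took 0.00771% of the counts in hy1 24 h replicate 1 and 0.00097% to 0.00553% in the other 17 libraries, and mitochondrial ones 0.00631% to 0.0441%. Reads of near-identical paralogs and of genes that overlap on opposite strands cannot be assigned with certainty. Floors cover counting error only, since reads from amplified libraries are not independent molecules. A gene with no read in the 3 libraries of a group was compared with a floor of 3 counts over the group, and its fold was given as a lower bound.

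R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 was used. One edgeR quasi-likelihood model with 6 group means and TMM scaling was fitted to the 18 libraries, with no replicate block, since the labels do not pair replicates by number. Comparisons were WT and hy1 at 12 h and 24 h against 0 h and at 24 h against 12 h, hy1 against WT at each time, and the interaction of genotype and light at 12 h and 24 h. P-values were two-sided and adjusted by Benjamini and Hochberg within each of the 11 comparisons, and a gene was called at adjusted p under 0.05. Log2 values are given ± standard error and levels as CPM ± SD.

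Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. The 23 lists held genes of light harvesting and photosystems, of tetrapyrrole and chlorophyll synthesis, of phytochrome chromophore synthesis, of photoreceptors and light signalling, induced by PIF factors or shade, of auxin response, of auxin synthesis and transport, and regulators of adventitious and lateral roots. Others held genes of the cell cycle and DNA replication, of flavonoid and anthocyanin synthesis, expansins and xyloglucan endotransglucosylases, the circadian clock, jasmonate, cytokinin, gibberellin, ethylene, iron deficiency and storage, secondary wall and xylem, and heat shock proteins. Markers of other tissue covered root hair and endodermis, shoot meristem, stomatal lineage, and seed reserves and their use. Of 504 listed members 496 carried the listed symbol at their locus in the annotation and were used, and 8 (PPOX1, DVR, UGT75C1, RVE6, FIT, GC1, HSP22 and HSP23.6) were left out. The counts of members given are of those measured. A further 4 groups, for phosphate starvation, dark and sugar starvation, rapid touch and wound response, and abscisic acid, were drawn up after the results were seen.

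Genes were named by a rule fixed before the data were examined. It took HY1, the chromophore list and the root regulators, the 5 largest rises and 5 largest falls per comparison among called genes with a mean of at least 5 CPM and, outside the interactions, no overlap between the groups of 3, and up to 4 members per list with the smallest adjusted p, or the largest change where none passed. Chance gives no overlap of 3 against 3 in 10% of cases. Genes outside the rule are named as chosen after their values were seen.

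Alternatives fixed before the data were examined were DESeq2 size factors and upper-quartile factors in edgeR, no filter and a stricter filter on counts, the DESeq2 Wald test, limma on log2(FPKM + 1) and log2(FPKM + 0.1) and without a filter on FPKM, the groups compared alone, a replicate block, organelle genes left out, adjusted p under 0.01, a fold of at least 2, and each library left out in turn. Where few libraries of a group were left, the fit assumes that they vary like the other groups. WT 12 h replicates 2 and 3 and WT 24 h replicate 3 were seen to stand apart, and the same results were computed without them, with an indicator term for them, and with each library corrected for its trend on exon length and GC content. The pipeline was tested on simulated counts with the spread and depth of hy1 against WT at 12 h. It called 9 of 67 genes changed 1.5-fold (13.4%), 42 of 67 changed 2-fold (62.7%), 65 of 67 changed 4-fold (97%) and 3 unchanged genes among 20698 genes in all. A raised list was called (adjusted p = 2.9e-34), and 0 of 20 random lists were. Genes were drawn independently and with no shift of the 3 libraries. False calls from correlated genes or that shift were not measured.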

Results

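Poly-A RNA was sequenced from Arabidopsis thaliana hypocotyls, the seedling stem between root and cotyledons, of the wild type (WT) and of hy1. The hy1 mutant lacks normal function of HY1, the haem oxygenase that makes the precursor of the phytochrome chromophore, so that phytochrome photoreceptors are impaired in it. Hypocotyls were taken in darkness (0 h) and after 12 h and 24 h in light, with 3 libraries in each of 6 groups. Total counts were 41028875, 41680952 and 44451246 in the WT 0 h libraries, 43548476, 38469946 and 49972216 at WT 12 h and 49547963, 41330808 and 41205294 at WT 24 h. In hy1 they were 43481881, 44565658 and 43920040 at 0 h, 59905064, 44015956 and 43217257 at 12 h and 51721733, 43964507 and 42472977 at 24 h. Sample titles named the WT libraries as mock and the hy1 libraries as before treatment or dark to light, and the genotypes used are those of the descriptions and count columns. A treatment that differed along with genotype could not be told apart from it. Libraries kept dark for 12 h or 24 h were not analysed here, so that a response to light could not be told apart from elapsed time, age or time of day. Of 32833 genes, 20955 were tested. Levels are given as CPM (counts scaled to library size, mean ± SD of 3 libraries) and changes as log2 fold changes ± standard error, from an edgeR fit of all 18 libraries. A gene rose or fell when its adjusted p was under 0.05 in the comparison, and a gene list was called when its camera adjusted p was under 0.05. Where a called list is given with counts of its members and no p with an estimated correlation, the call also held with that correlation. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples.

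WT 12 h replicates 2 and 3 and WT 24 h replicate 3 stood apart from the remaining libraries of their groups. Across genes, pairs of libraries that mixed these 3 with the others of a group correlated at r = 0.9475 to 0.9713, and the 14 other pairs within groups at 0.9781 to 0.9913, genes not being independent replicates. Genes with exon lengths of 401 to 800 bases took 1.36% to 1.83% of the counts in the 3 libraries and 1.93% to 2.86% in the other 15. Photosystem genes lay lower in them, by a median log2 difference of -0.603 at 12 h and -1.009 at 24 h from the remaining libraries of their groups. Regulators of adventitious and lateral roots lay higher, by medians of 0.586 at 12 h and 0.58 at 24 h, as did jasmonate genes (0.521 and 0.42). Each count of genes is therefore also given without these 3 libraries, which leaves 1 WT 12 h library and 2 WT 24 h libraries.

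**Figure D1:**
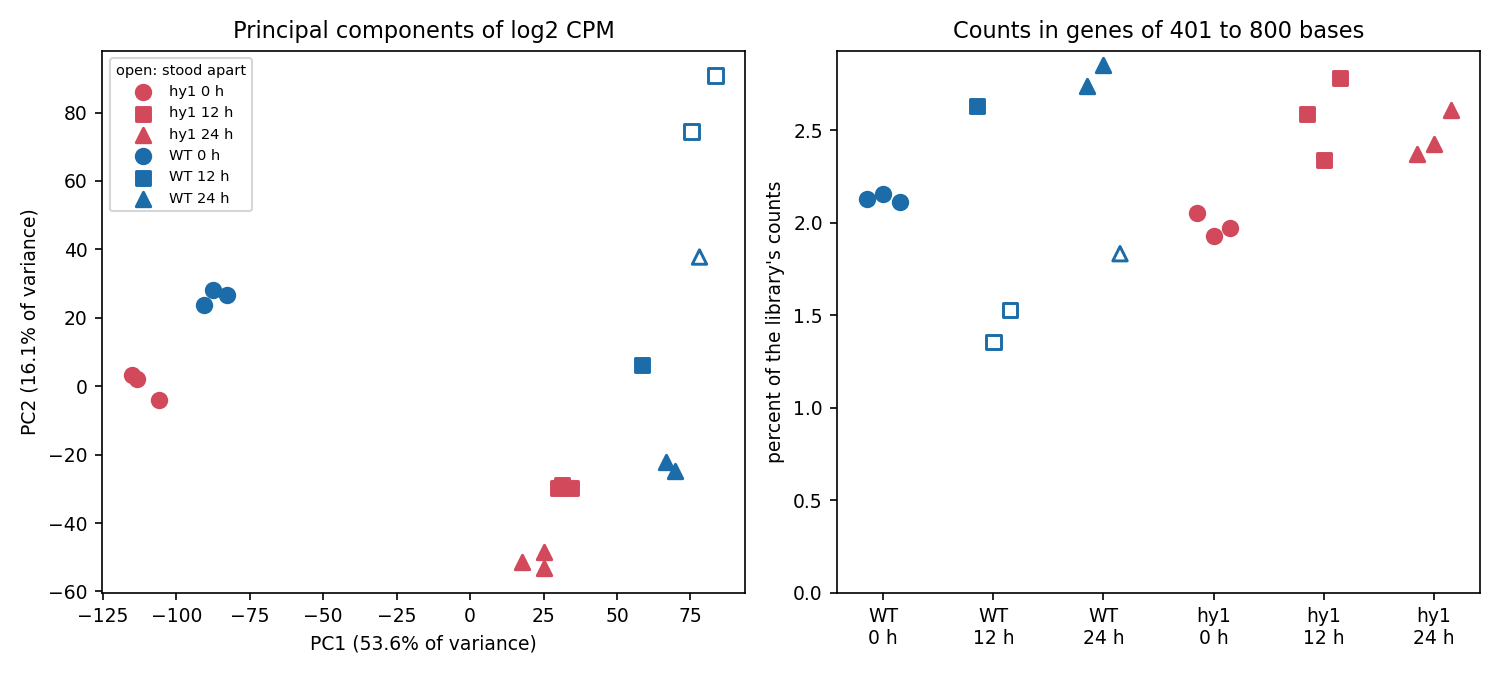
Principal components 1 (53.6% of the variance) and 2 (16.1%) of log2 CPM in the 18 libraries, and the percent of each library's counts in genes of 401 to 800 bases. The 3 WT libraries drawn with open symbols lie at 37.8 to 90.8 on component 2, above the other WT libraries in light, and at 1.36% to 1.83% on the second axis.

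HY1 (AT2G26670), the gene named in the series title, lies on chromosome 2 (TAIR10, 11341548 to 11343693, plus strand, exon length 1416 bases). Its level was 45 ± 2.78 CPM in WT in the dark, 27.6 ± 5.62 at 12 h and 39.2 ± 4.79 at 24 h. In hy1 it was 34.4 ± 2.47, 21.9 ± 2.14 and 18.9 ± 0.545 CPM at the same times, so that transcripts of the gene were present in every hy1 library. HY1 was lower in hy1 at 0 h (-0.39 ± 0.13, adjusted p = 0.041) and at 24 h (-1.05 ± 0.13, adjusted p = 6.6e-05), while the value at 12 h was -0.34 ± 0.13, adjusted p = 0.06. The call at 0 h was lost when any 1 of its 6 libraries was left out (adjusted p = 0.053 to 0.12). At 12 h the gene passed without the 3 libraries that stood apart (adjusted p = 0.0015), without WT 12 h replicate 3 (0.03) and without hy1 12 h replicate 1 (0.042). The interaction at 24 h was -0.66 ± 0.18, adjusted p = 0.036, a call lost when WT 0 h or WT 24 h replicate 1 or 2, hy1 0 h replicate 1 or 2, or any hy1 24 h library was left out (adjusted p = 0.069 to 0.094). It was also lost with upper-quartile factors (adjusted p = 0.076), with limma on log2(FPKM + 1) (0.064), on log2(FPKM + 0.1) (0.065) and on log2(FPKM + 1) with no filter (0.068). In WT it fell at 12 h (-0.70 ± 0.13), with -0.20 ± 0.13 at 24 h, and in hy1 it fell at 12 h (-0.65 ± 0.13) and 24 h (-0.86 ± 0.13). The labels do not name the allele. The other members of the chromophore list, HO2 (AT2G26550), another haem oxygenase, and HY2 (AT3G09150), phytochromobilin synthase, did not pass between genotypes at any time.

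**Figure D2:**
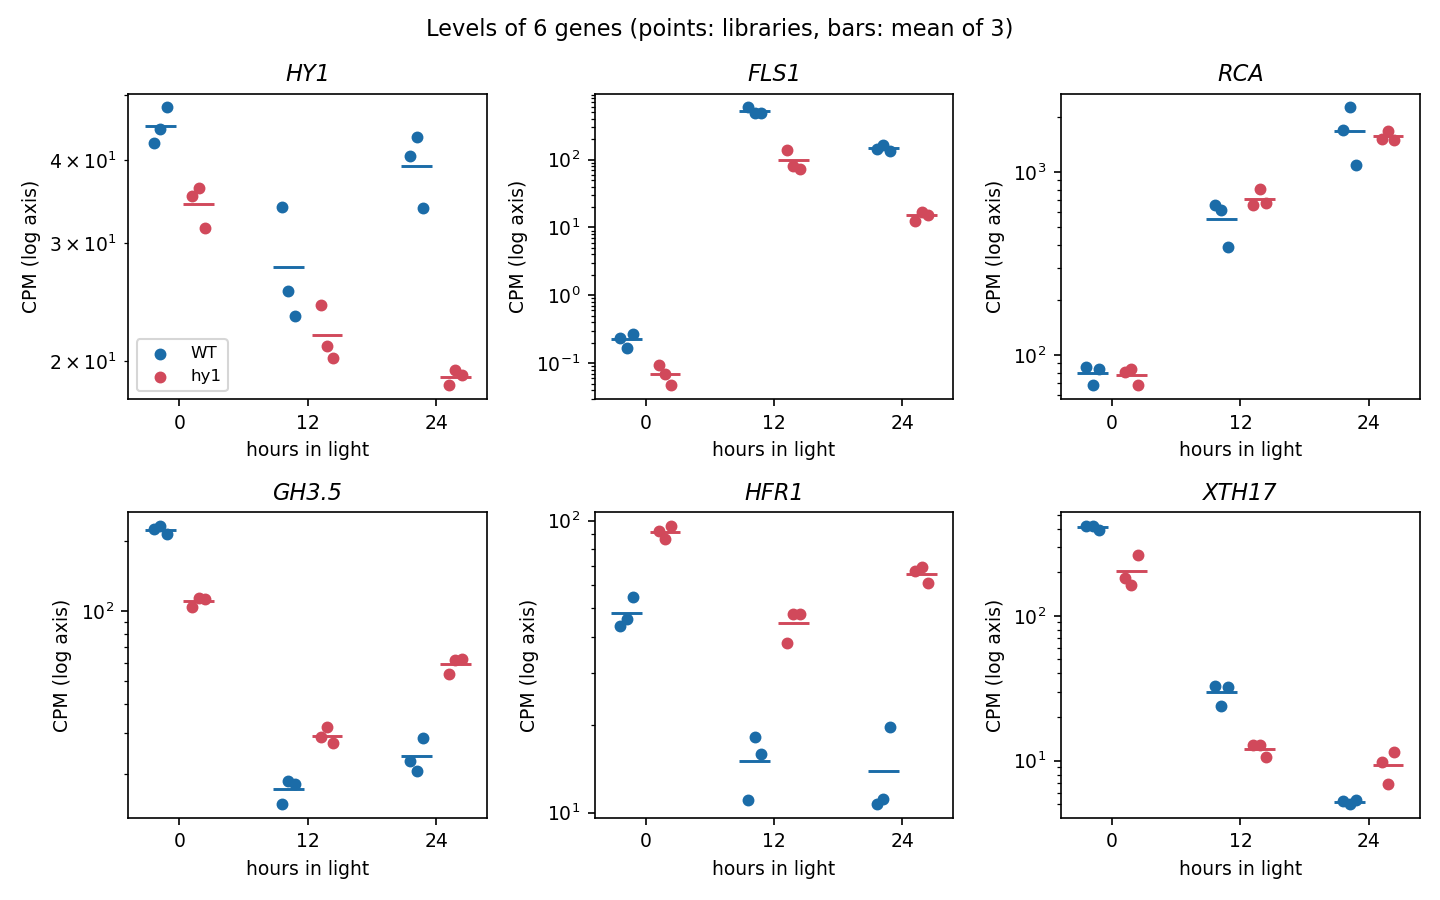
Levels of HY1, FLS1, RCA, GH3.5, HFR1 and XTH17 in each of the 18 libraries, in CPM on a log axis against hours in light, with the mean of 3 libraries per group as a bar. HY1 ran at 31.6 to 36.3 CPM in the 3 hy1 libraries at 0 h and at 18.4 to 19.4 CPM at 24 h.

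WT at 12 h against WT at 0 h asks what changed in light in hypocotyls with intact phytochrome. Flavonoid genes rose steeply and genes of auxin response, shade response and wall loosening fell. CHS (AT5G13930), chalcone synthase, the entry enzyme of flavonoid synthesis, went from 0.481 ± 0.123 to 3800 ± 550 CPM (12.94 ± 0.45, adjusted p = 1e-11), and FLS1 (AT5G08640), flavonol synthase, from 0.224 ± 0.0519 to 522 ± 59.8 CPM (11.17 ± 0.32). In the flavonoid list 21 of 23 members rose and 1 fell (21 and 1 adjusted over the list alone; adjusted p = 8.7e-10). DFR (AT5G42800), of the anthocyanin branch, had no read in the 3 WT 0 h libraries and was at least 700-fold higher at 12 h, against a floor of 3 counts over the group. Of the auxin response genes 36 of 45 members fell and 1 rose (36 and 1 adjusted over the list alone; adjusted p = 7.2e-13). Examples were GH3.5 (AT4G27260), which conjugates auxin (-3.71 ± 0.13), GH3.3 (AT2G23170, -4.22 ± 0.24) and the Aux/IAA gene IAA19 (AT3G15540, -5.14 ± 0.33). Among genes induced by PIF factors or shade 15 of 16 members fell and 0 rose (15 and 0 adjusted over the list alone; adjusted p = 3.9e-10). The homeobox gene HAT2 (AT5G47370) changed by -2.70 ± 0.10. Among expansins and xyloglucan endotransglucosylases 16 of 21 members fell and 2 rose (17 and 2 adjusted over the list alone; adjusted p = 3.3e-08). Examples were XTH17 (AT1G65310, -3.79 ± 0.21) and XTH18 (-4.16 ± 0.23).

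Genes of the photosynthetic apparatus rose as well. In the photosystem list 31 of 44 members rose and 0 fell (34 and 0 adjusted over the list alone; adjusted p = 3.3e-07, or 0.53 with an estimated correlation). Rubisco activase, RCA (AT2G39730), changed by 2.81 ± 0.24 and the photosystem I subunit PSAF (AT1G31330) by 2.03 ± 0.19. In chlorophyll synthesis 16 of 24 members rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 3e-06, or 0.21 with an estimated correlation). An example was the magnesium chelatase subunit GUN5 (AT5G13630, 3.18 ± 0.21). The member that fell was PORA, the protochlorophyllide reductase of etiolated seedlings, chosen after its values were seen, from 9.64 ± 7.2 to 0.0137 ± 0.0238 CPM. In photoreceptors and light signalling 21 of 38 members rose and 8 fell (21 and 9 adjusted over the list alone; adjusted p = 0.00048, or 0.2 with an estimated correlation), and the transcription factors HY5 (AT5G11260, 2.58 ± 0.14) and HYH (5.12 ± 0.21) rose. In auxin synthesis and transport 17 of 28 members fell and 2 rose (17 and 2 adjusted over the list alone; adjusted p = 0.00031). The synthesis gene YUC9 (AT1G04180) changed by -2.27 ± 0.21. PIN5 (AT5G16530), an auxin carrier of the endoplasmic reticulum, went against the list: it had no read at WT 0 h and was at least 79-fold higher at 12 h. In the ethylene list 11 of 17 members fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.00053, or 0.14 with an estimated correlation). Of the regulators of adventitious and lateral roots 11 of 32 members rose and 6 fell (12 and 6 adjusted over the list alone; adjusted p = 0.41), so that the list was not called. WOX11 (AT3G03660), of adventitious root founder cells, rose (3.67 ± 0.61), as did PUCHI (3.39 ± 0.64), while ARF10 (AT2G28350, -1.07 ± 0.11) fell. Root regulators lay higher in WT 12 h replicates 2 and 3, and without the 3 libraries PUCHI was at 1.33. In the chromophore list 2 of 3 members rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.6). Among shoot meristem markers 2 of 3 members rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.73). In total 5938 genes rose and 5302 fell, 5002 of the 11240 by at least 2-fold. Without the 3 libraries that stood apart 10219 changed, and 7744 were called with and without them.

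WT at 24 h against WT at 0 h extends the light response to a full day. Photosystem genes had risen further, flavonoid genes stayed high, and shade genes low. In the photosystem list 42 of 44 members rose and 0 fell (42 and 0 adjusted over the list alone; adjusted p = 1.9e-16, or 0.18 with an estimated correlation). RCA changed by 4.40 ± 0.26 and PSAF by 2.45 ± 0.20. In chlorophyll synthesis 19 of 24 members rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 2.5e-09, or 0.095 with an estimated correlation). GUN5 changed by 3.81 ± 0.22. CHS stood at 1370 ± 159 CPM (11.47 ± 0.43, adjusted p = 3.1e-11) and FLS1 at 149 ± 14.6 CPM (9.36 ± 0.30). In the flavonoid list 19 of 23 members rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 1.3e-06). Auxin response genes were still down: 35 of 45 members fell and 3 rose (36 and 3 adjusted over the list alone; adjusted p = 5.6e-13), GH3.5 having changed by -3.23 ± 0.13 and IAA19 by -4.57 ± 0.32. The PIF and shade genes fell without exception, as 16 of 16 members fell and 0 rose (16 and 0 adjusted over the list alone; adjusted p = 5.1e-12). In wall loosening 17 of 21 members fell and 3 rose (17 and 3 adjusted over the list alone; adjusted p = 9.8e-09). XTH17 changed by -6.29 ± 0.23.

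Markers of the endodermis, the inner root sheath whose Casparian strip genes are also read in hypocotyls, fell at 24 h in WT. In the list of root hair and endodermis markers 7 of 10 members fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 3.8e-05). The Casparian strip gene CASP5 (AT5G15290) changed by -7.20 ± 0.32. Secondary wall and xylem genes fell too: 9 of 13 members fell and 0 rose (9 and 0 adjusted over the list alone; adjusted p = 0.0052, or 0.27 with an estimated correlation). Examples were the cellulose synthases CESA7 (-1.05 ± 0.19) and CESA8 (-0.84 ± 0.17). In the cell cycle and DNA replication list 10 of 38 members rose and 1 fell (7 and 0 adjusted over the list alone; adjusted p = 0.03, or 0.45 with an estimated correlation). The replication factor MCM3 (AT5G46280) changed by 0.73 ± 0.11. In the ethylene list 12 of 17 members fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 3.8e-05), and ACS5 (AT5G65800), an enzyme of ethylene synthesis with no read left in 3 libraries, was at least 694-fold lower. In auxin synthesis and transport 18 of 28 members fell and 2 rose (18 and 2 adjusted over the list alone; adjusted p = 4.6e-05). In light signalling 19 of 38 members rose and 9 fell (19 and 9 adjusted over the list alone; adjusted p = 0.01, or 0.27 with an estimated correlation). Cytokinin genes went both ways: 3 of 17 members rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.95), the oxidase CKX5 (-2.47 ± 0.18) falling and the synthesis gene IPT3 (1.55 ± 0.19) rising. In all 5159 genes rose and 4842 fell, 4444 of the 10001 by at least 2-fold. Without the 3 libraries 12557 changed, 9630 of them shared.

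WT at 24 h against WT at 12 h separates early from later changes in light. The morning clock genes CCA1 and LHY rose between these times, while flavonoid and endodermis genes came down. CCA1 (AT2G46830) went from 4.82 ± 0.573 to 75.6 ± 3.92 CPM (3.97 ± 0.20, adjusted p = 1.4e-08), and LHY (AT1G01060) rose likewise (3.89 ± 0.23). In the clock list 5 of 22 members rose and 11 fell (5 and 11 adjusted over the list alone; adjusted p = 0.25). Of the flavonoid genes 12 of 23 members fell and 0 rose (15 and 0 adjusted over the list alone; adjusted p = 1.6e-15). Examples were TT7 (AT5G07990), flavonoid 3'-hydroxylase (-2.56 ± 0.21), and FLS1 (-1.81 ± 0.20). Of the endodermis markers 7 of 10 members fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 2e-14). CASP5 changed by -6.79 ± 0.31. Of the secondary wall genes 10 of 13 members fell and 0 rose (10 and 0 adjusted over the list alone; adjusted p = 2.2e-10). The xylem regulator VND6 (AT5G62380) changed by -1.38 ± 0.14. Photosystem genes rose further, as 23 of 44 members rose and 0 fell (37 and 0 adjusted over the list alone; adjusted p = 1.8e-17, or 0.3 with an estimated correlation), and RCA changed by 1.59 ± 0.23. The 3 libraries that stood apart, 2 of them at 12 h, held less of these photosystem transcripts than the rest of their groups. In chlorophyll synthesis 5 of 24 members rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 9.2e-06, or 0.3 with an estimated correlation). In light signalling 7 of 38 members fell and 2 rose (17 and 4 adjusted over the list alone; adjusted p = 8.6e-05, or 0.21 with an estimated correlation), and HY5 fell (-0.90 ± 0.13). No cell cycle gene passed, though that list was called upward (adjusted p = 0.0037, and adjusted p = 0.47 with an estimated correlation).

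This contrast called 1902 genes, 769 up and 1133 down, and the count depended on which libraries entered it. Without the 3 libraries it was 964, 760 of them shared, and with its 6 libraries fitted alone 111, RCA (adjusted p = 0.13) and HY5 (adjusted p = 0.098) no longer among them. It was 8279 without WT 12 h replicate 1 and 5443 without WT 24 h replicate 3. It was 1086 and 1132 without WT 12 h replicates 2 and 3, and 935 and 939 without WT 24 h replicates 1 and 2.

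The comparison of hy1 at 12 h with hy1 at 0 h asks which of these changes were seen in light with impaired phytochrome. Most flavonoid and photosystem genes rose and most auxin and shade genes fell. CHS went from 0.11 ± 0.118 to 725 ± 171 CPM (12.66 ± 0.47, adjusted p = 2.9e-11) and FLS1 from 0.0701 ± 0.0239 to 97.6 ± 34.8 CPM (10.39 ± 0.34). In the flavonoid list 17 of 23 members rose and 1 fell (18 and 1 adjusted over the list alone; adjusted p = 1.6e-06, or 0.06 with an estimated correlation). In the photosystem list 41 of 44 members rose and 0 fell (41 and 0 adjusted over the list alone; adjusted p = 4.3e-18, or 0.18 with an estimated correlation). PSAF changed by 2.72 ± 0.20. In chlorophyll synthesis 19 of 24 members rose and 2 fell (19 and 2 adjusted over the list alone; adjusted p = 1.5e-07, or 0.16 with an estimated correlation). GUN5 changed by 4.02 ± 0.22. Among auxin response genes 29 of 45 members fell and 3 rose (29 and 5 adjusted over the list alone; adjusted p = 3.5e-06, or 0.089 with an estimated correlation), GH3.5 changing by -1.92 ± 0.12 and IAA19 by -2.93 ± 0.30. Among PIF and shade genes 12 of 16 members fell and 0 rose (12 and 0 adjusted over the list alone; adjusted p = 5.1e-06). HAT2 changed by -1.42 ± 0.096.

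Ethylene genes fell in hy1, where 13 of 17 members fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 2.7e-07). They included EBF1 (AT2G25490, -1.69 ± 0.090) and EBF2 (-2.04 ± 0.15), F-box genes that restrain ethylene signalling, and the receptor ETR2 (-2.18 ± 0.16). In wall loosening 13 of 21 members fell and 4 rose (13 and 4 adjusted over the list alone; adjusted p = 0.00012, or 0.077 with an estimated correlation). XTH17 changed by -4.07 ± 0.21. In auxin synthesis and transport 16 of 28 members fell and 3 rose (16 and 3 adjusted over the list alone; adjusted p = 0.0061, or 0.13 with an estimated correlation). In light signalling 22 of 38 members rose and 9 fell (22 and 10 adjusted over the list alone; adjusted p = 0.01, or 0.3 with an estimated correlation). The cell cycle list was called upward, as 9 of 38 members rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 0.037, or 0.43 with an estimated correlation). Among clock genes PRR7 (AT5G02810, -2.35 ± 0.18) and GI (AT1G22770, -1.74 ± 0.18) fell, and 6 of 22 members rose and 9 fell (6 and 11 adjusted over the list alone; adjusted p = 0.14). All markers of seed reserve use fell: 3 of 3 members fell and 0 rose (3 and 0 adjusted over the list alone; adjusted p = 0.01, or 0.18 with an estimated correlation), isocitrate lyase, ICL (AT3G21720), by a log2 change of -2.66 ± 0.37. Without the 3 WT libraries the seed list gave adjusted p = 0.05. In the heat shock list 4 of 7 members rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.053). An example was HSP70 (1.19 ± 0.14). In hy1 4809 genes rose and 4454 fell by 12 h, 3883 of the 9263 by at least 2-fold, and 12980 changed once the 3 WT libraries left the fit.

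hy1 at 24 h against hy1 at 0 h gives the mutant's response after a day. Nearly the whole photosystem list had risen, flavonoid genes kept part of their rise, and ethylene, endodermis and secondary wall genes were below their dark level. In the photosystem list 43 of 44 members rose and 0 fell (43 and 0 adjusted over the list alone; adjusted p = 3.1e-23, or 0.14 with an estimated correlation). RCA changed by 4.34 ± 0.26. In chlorophyll synthesis 20 of 24 members rose and 2 fell (20 and 3 adjusted over the list alone; adjusted p = 7e-09, or 0.14 with an estimated correlation). An example was the chelatase subunit CHLI1 (2.93 ± 0.23). CHS changed by 10.14 ± 0.44, and in the flavonoid list 16 of 23 members rose and 1 fell (17 and 2 adjusted over the list alone; adjusted p = 0.0011, or 0.14 with an estimated correlation). Of the auxin response genes 19 of 45 members fell and 4 rose (19 and 4 adjusted over the list alone; adjusted p = 0.0025, or 0.23 with an estimated correlation). IAA6 (AT1G52830) changed by -2.03 ± 0.27. Of the PIF and shade genes 11 of 16 members fell and 0 rose (13 and 0 adjusted over the list alone; adjusted p = 2.4e-06). An example was YUC9 (-3.99 ± 0.22). Of the ethylene genes 13 of 17 members fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 7.3e-08). EBF1 changed by -1.92 ± 0.091. In the endodermis list 7 of 10 members fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 0.00026, or 0.14 with an estimated correlation). CASP5 changed by -5.83 ± 0.30. In the secondary wall list 11 of 13 members fell and 0 rose (11 and 0 adjusted over the list alone; adjusted p = 7e-04, or 0.23 with an estimated correlation). The laccase gene LAC4 (AT2G38080) changed by -1.52 ± 0.28. In the cell cycle list 12 of 38 members rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 0.0013, or 0.25 with an estimated correlation). MCM3 changed by 0.84 ± 0.11. Of the jasmonate genes 11 of 21 members fell and 3 rose (11 and 3 adjusted over the list alone; adjusted p = 0.047, or 0.4 with an estimated correlation), and without the 3 WT libraries the list gave adjusted p = 0.059. The repressor gene JAZ1 (AT1G19180) was among those that fell (-2.67 ± 0.49). Counts were 4273 genes up and 4211 down, 3548 of the 8484 by at least 2-fold, and 12298 in all without the 3 WT libraries.

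The later part of the mutant's response is given by hy1 at 24 h against hy1 at 12 h. Clock genes went both ways, and flavonoid and endodermis genes came down. PRR9 (AT2G46790) rose (3.79 ± 0.20, adjusted p = 4.2e-08) and BOA (AT5G59570) fell (-2.22 ± 0.11), and in the clock list 10 of 22 members rose and 7 fell (11 and 7 adjusted over the list alone; adjusted p = 0.0026, or 0.2 with an estimated correlation). Of the flavonoid genes 12 of 23 members fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 2e-16). FLS1 changed by -2.69 ± 0.21. Of the endodermis markers 6 of 10 members fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 1.1e-11). CASP5 changed by -4.41 ± 0.29. Among auxin response genes 9 of 45 members rose and 1 fell (13 and 2 adjusted over the list alone; adjusted p = 4.2e-07, or 0.096 with an estimated correlation), GH3.3 changing by 2.03 ± 0.22 and GH3.5 by 1.02 ± 0.12. In secondary walls 6 of 13 members fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 4.2e-07, or 0.11 with an estimated correlation). The wall regulator MYB83 (AT3G08500) changed by -1.13 ± 0.24, and did not pass without hy1 24 h replicate 1 (adjusted p = 0.072). In the photosystem list 3 of 44 members rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 1.7e-05, or 0.5 with an estimated correlation). Root regulators were called upward although 1 of 32 members rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.019, or 0.4 with an estimated correlation). The contrast called 1025 genes, 493 up and 532 down, 384 of them at least 2-fold. It called 3117 with its 6 libraries fitted alone, 3500 without the 3 WT libraries, and 522 to 663 with any 1 of its own 6 libraries left out.

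hy1 against WT at 0 h asks whether the genotypes already differed in the dark. Most auxin response, wall loosening and photosystem genes were lower in hy1. GH3.5 stood at 110 ± 5.36 CPM in hy1 and 225 ± 8.81 in WT (-1.02 ± 0.12, adjusted p = 3.3e-05). In the auxin response list 27 of 45 members were lower and 3 higher (29 and 3 adjusted over the list alone; adjusted p = 4.6e-10, or 0.052 with an estimated correlation). IAA5 (AT1G15580) differed by -2.08 ± 0.25. Of the photosystem genes 26 of 44 members were lower and 0 higher (30 and 0 adjusted over the list alone; adjusted p = 8.4e-08, or 0.36 with an estimated correlation). PSAF differed by -1.09 ± 0.19. In the PIF and shade list 9 of 16 members were lower and 4 higher (11 and 4 adjusted over the list alone; adjusted p = 0.0019, or 0.052 with an estimated correlation). HAT3 (-1.42 ± 0.15) was lower and YUC9 (1.66 ± 0.19) higher. In wall loosening 12 of 21 members were lower and 2 higher (13 and 3 adjusted over the list alone; adjusted p = 0.00011, or 0.089 with an estimated correlation). The expansin EXPA1 (AT1G69530) differed by -0.94 ± 0.16. In the cell cycle list 12 of 38 members were lower and 0 higher (15 and 0 adjusted over the list alone; adjusted p = 3.7e-05, or 0.17 with an estimated correlation). MCM3 differed by -0.60 ± 0.11. In auxin synthesis and transport 8 of 28 members were lower and 3 higher (8 and 3 adjusted over the list alone; adjusted p = 0.018, or 0.17 with an estimated correlation). An example was the influx carrier LAX3 (-0.99 ± 0.11).

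Among clock genes 11 of 22 members were higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.00011, or 0.09 with an estimated correlation). CCA1 differed by 1.16 ± 0.17 and RVE8 (AT3G09600) by 0.82 ± 0.14. Among jasmonate genes 9 of 21 members were higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.0029, or 0.2 with an estimated correlation). Examples were JAZ7 (2.52 ± 0.45) and the storage protein VSP1 (1.81 ± 0.25). In the ethylene list 10 of 17 members were higher and 4 lower (10 and 5 adjusted over the list alone; adjusted p = 0.018, or 0.23 with an estimated correlation), EBF1 (1.39 ± 0.089) being higher and the synthase ACS8 (-3.68 ± 0.41) lower. Heat shock genes were lower: 4 of 7 members were lower and 0 higher (4 and 0 adjusted over the list alone; adjusted p = 0.0039, or 0.17 with an estimated correlation). HSP70 differed by -1.08 ± 0.14. Of the stomatal markers 2 of 6 members were lower and 0 higher (4 and 0 adjusted over the list alone; adjusted p = 0.0049, or 0.17 with an estimated correlation). Of the markers of reserve use 2 of 3 members were higher and 0 lower (2 and 0 adjusted over the list alone; adjusted p = 0.018, or 0.2 with an estimated correlation). The latter included PCK1 (AT4G37870), a gluconeogenic enzyme (1.62 ± 0.12). Among root regulators 11 of 32 members were higher and 3 lower (11 and 3 adjusted over the list alone; adjusted p = 0.15). WOX11 stood at 2.96 ± 2.01 CPM in hy1 and 0.183 ± 0.124 in WT (3.98 ± 0.61, adjusted p = 0.00025), and PLT1 (2.73 ± 0.38) and BBM (2.63 ± 0.42) of the root meristem were higher too. Among called genes with a mean of at least 5 CPM and no overlap between the groups, rises were led by AT1G49570 (5.40 ± 0.62), AT4G34380 (4.42 ± 0.32), AT4G07820 (4.12 ± 0.31), AT1G19900 (3.86 ± 0.38) and SOM (3.76 ± 0.35). SOM (AT1G03790) encodes a repressor of seed germination. The falls were led by UGT74E2 (-4.16 ± 0.43), RGF9 (-4.15 ± 0.34), AT4G28780 (-4.11 ± 0.32), ICS2 (-4.04 ± 0.25) and AT1G78450 (-4.01 ± 0.67), where ICS2 is an isochorismate synthase. In all 2560 genes were higher in hy1 and 2594 lower, 1763 of the 5154 by at least 2-fold. The count was 9750 without the 3 WT libraries, none of which entered this contrast, 9154 with its 6 libraries fitted alone and 3424 without WT 0 h replicate 1.

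**Figure D3:**
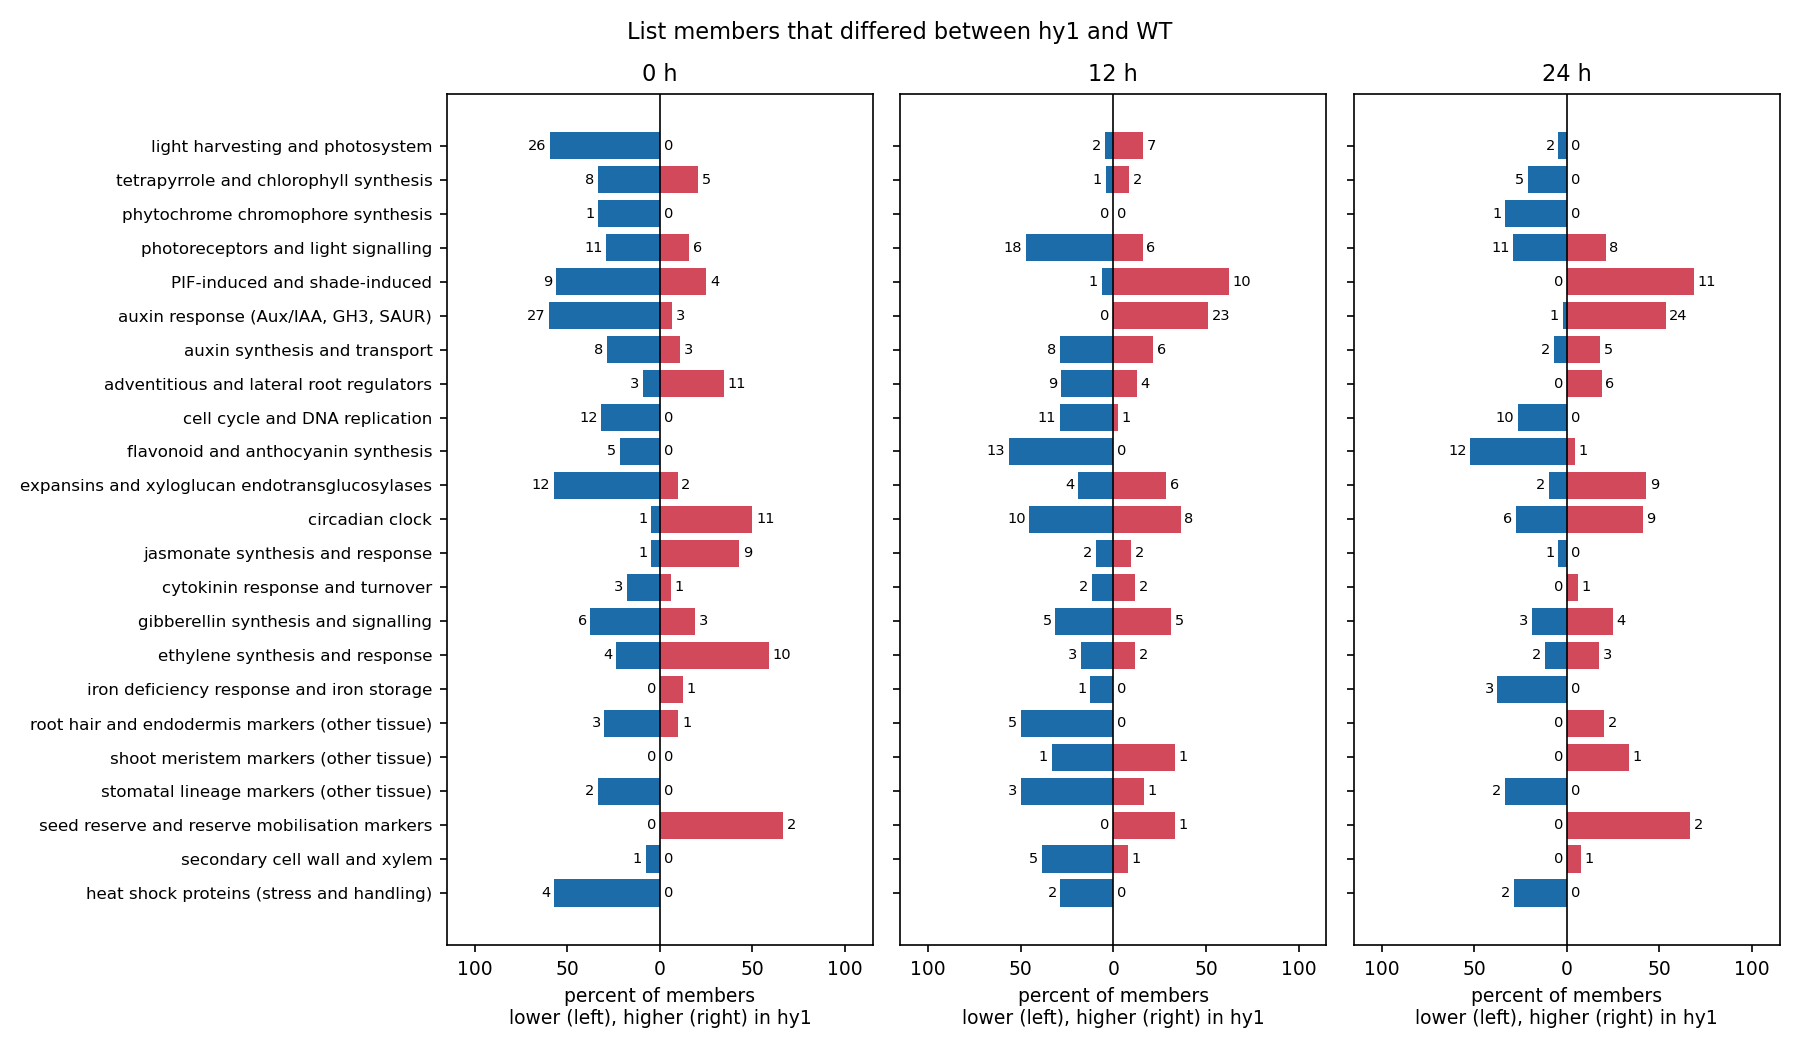
Members of each of the 23 lists that were higher (to the right) or lower (to the left) in hy1 than in WT at 0 h, 12 h and 24 h, as a percent of the list's measured members, with the counts beside the bars. In the auxin response list 27 of 45 members were lower at 0 h, 23 were higher at 12 h and 24 were higher at 24 h.

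hy1 against WT at 12 h asks how the genotypes differed after 12 h in light. Clock genes differed by large factors, most flavonoid genes were lower in hy1, and most auxin response and shade genes were now higher. CCA1 stood at 59.9 ± 13.2 CPM in hy1 and 4.82 ± 0.573 in WT (3.64 ± 0.19, adjusted p = 4.4e-08), LHY was higher (3.72 ± 0.23), and the evening gene GI was lower (-2.94 ± 0.19). In the clock list 8 of 22 members were higher and 10 lower (9 and 10 adjusted over the list alone; adjusted p = 0.74), without a common direction. Of the flavonoid genes 13 of 23 members were lower and 0 higher (13 and 0 adjusted over the list alone; adjusted p = 1e-07). TT7 differed by -2.83 ± 0.21 and FLS1 by -2.42 ± 0.20. Of the auxin response genes 23 of 45 members were higher and 0 lower (26 and 0 adjusted over the list alone; adjusted p = 3.5e-05, or 0.2 with an estimated correlation). Examples were SAUR16 (AT4G38860, 3.35 ± 0.44) and SAUR50 (1.99 ± 0.30), small auxin-induced genes. Of the PIF and shade genes 10 of 16 members were higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.00034). HFR1 (AT1G02340), a brake on PIF factors, differed by 1.58 ± 0.21. In light signalling 18 of 38 members were lower and 6 higher (18 and 7 adjusted over the list alone; adjusted p = 0.00034, or 0.25 with an estimated correlation). Examples were PIF7 (AT5G61270, -2.36 ± 0.23) and PIF4 (-1.70 ± 0.20), which drive elongation in shade.

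Of the photosystem genes 7 of 44 members were higher and 2 lower (6 and 0 adjusted over the list alone; adjusted p = 0.0088, or 0.93 with an estimated correlation), and without the 3 libraries, in which these genes lay lower, adjusted p = 0.21. Of the endodermis markers 5 of 10 members were lower and 0 higher (5 and 0 adjusted over the list alone; adjusted p = 0.0088, or 0.33 with an estimated correlation). CASP5 differed by -2.09 ± 0.23, and the list gave adjusted p = 0.13 without the 3 libraries. Among stomatal markers 1 of 6 members were higher and 3 lower (2 and 3 adjusted over the list alone; adjusted p = 0.83). In the root regulator list 4 of 32 members were higher and 9 lower (4 and 10 adjusted over the list alone; adjusted p = 0.68), so that the list was not called. ARF10 was higher (0.62 ± 0.11), and ARF7 (AT5G20730), an auxin response factor of lateral root formation, was lower with all libraries (-1.10 ± 0.25) and did not pass without the 3 (-0.25, adjusted p = 0.15). Among called genes of at least 5 CPM with no overlap rises were led by GLYI4 (4.27 ± 0.26), AT4G07820 (4.16 ± 0.33), TIP2;3 (4.12 ± 0.38), AT1G67865 (adjusted p = 6.1e-07) and AT1G67105 (3.83 ± 0.30), and falls by 4CL3 (-3.52 ± 0.40), AT5G14920 (-3.42 ± 0.60), AT2G34810 (-3.26 ± 0.45), CGA1 (-3.03 ± 0.48) and AT2G22590 (-2.99 ± 0.33). Without the 3 libraries 4CL3 was at -2.38, AT5G14920 at -1.41 and AT2G34810 at -2.19. Here 4CL3 is a ligase of phenylpropanoid synthesis and CGA1 (AT4G26150) a GATA factor of chloroplast development. In all 3129 genes were higher in hy1 and 3724 lower, 2062 of the 6853 by at least 2-fold. Without the 3 libraries 4085 were called, 2629 of them shared, and the 6 libraries fitted alone called 1496. The count was 11090 without WT 12 h replicate 1, 4479 without replicate 2 and 4057 without replicate 3. Limma on log2(FPKM + 1) moved the median of all genes from 0.012 to 0.11. It moved the percent of called genes that were higher in hy1 from 45.7 to 67.2, with scaling, transform and model changed together.

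**Figure D4:**
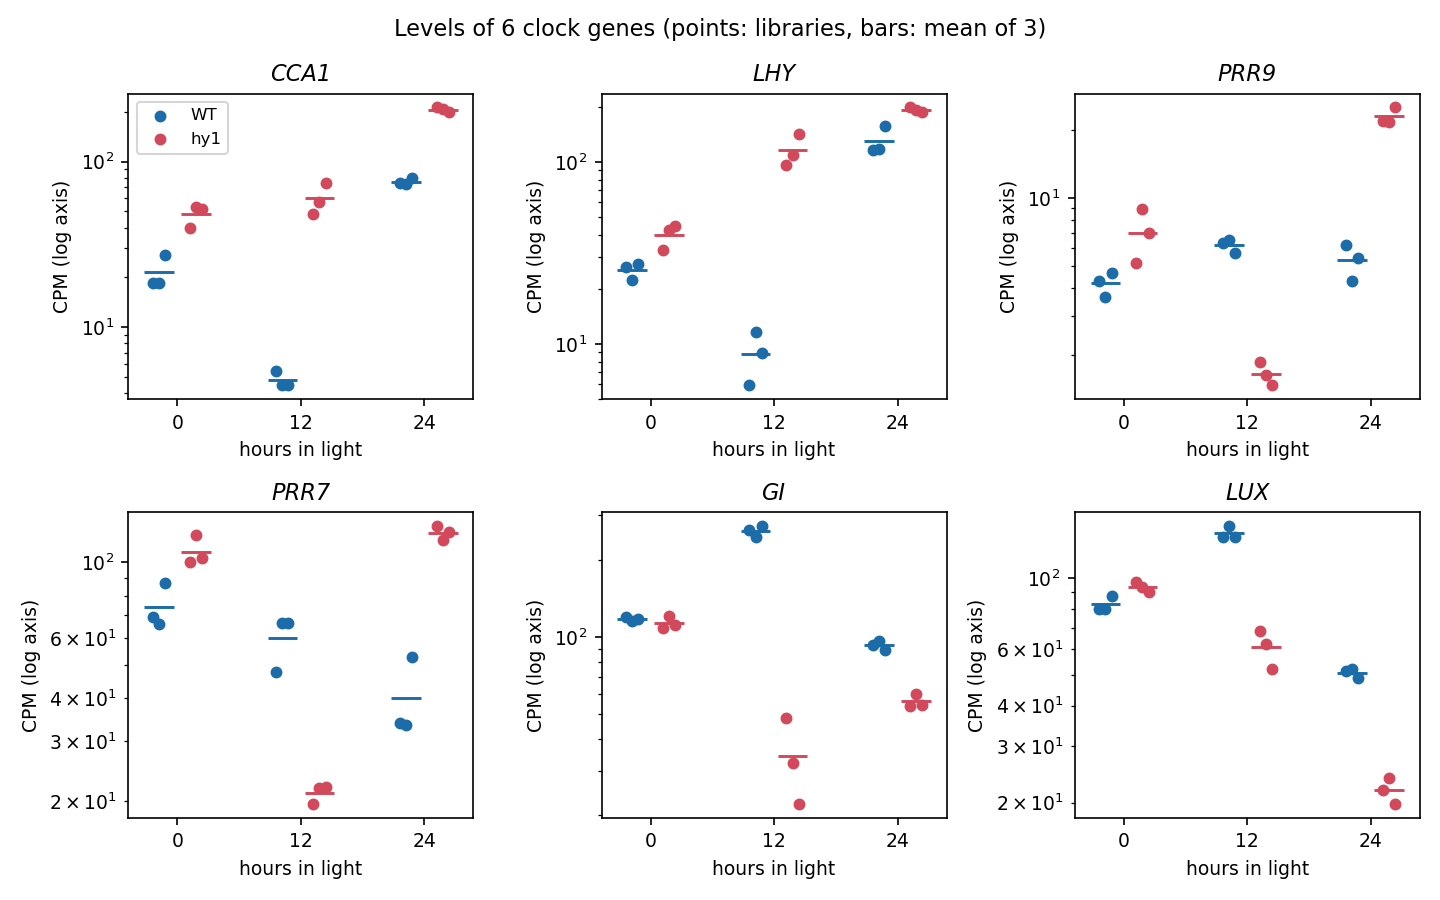
Levels of the clock genes CCA1, LHY, PRR9, PRR7, GI and LUX in each library, in CPM on a log axis against hours in light, with the mean of 3 libraries per group as a bar. At 12 h CCA1 and LHY were higher in all 3 hy1 libraries than in all 3 WT libraries, and GI and PRR9 lower.

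hy1 against WT at 24 h gives the difference after a day of light. Most auxin response and shade genes were higher in hy1, and most flavonoid genes lower. GH3.5 stood at 59.2 ± 4.8 CPM in hy1 and 23.9 ± 4.14 in WT (1.31 ± 0.12, adjusted p = 4.3e-06), and GH3.3 (2.26 ± 0.22) and SAUR16 (4.48 ± 0.42) were higher too. In the auxin response list 24 of 45 members were higher and 1 lower (27 and 1 adjusted over the list alone; adjusted p = 1.7e-10). Among PIF and shade genes 11 of 16 members were higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 2.5e-07). HFR1 differed by 2.25 ± 0.22 and HAT2 by 0.80 ± 0.096. In wall loosening 9 of 21 members were higher and 2 lower (11 and 2 adjusted over the list alone; adjusted p = 0.0046, or 0.18 with an estimated correlation). Examples were EXPA8 (AT2G40610, 2.85 ± 0.47) and XTH19 (AT4G30290, 2.05 ± 0.30). Of the flavonoid genes 12 of 23 members were lower and 1 higher (13 and 1 adjusted over the list alone; adjusted p = 9.6e-09). CHS differed by -3.45 ± 0.29 and FLS1 by -3.30 ± 0.21. The flavonoid gene that was higher is MYBL2 (AT1G71030), a repressor of the pathway, chosen after its values were seen (2.45 ± 0.30). Of the cell cycle genes 10 of 38 members were lower and 0 higher (10 and 0 adjusted over the list alone; adjusted p = 0.0011, or 0.36 with an estimated correlation). MCM3 differed by -0.50 ± 0.11. Of the iron genes 3 of 8 members were lower and 0 higher (3 and 0 adjusted over the list alone; adjusted p = 0.0047, or 0.06 with an estimated correlation). Examples were nicotianamine synthase, NAS4 (AT1G56430, -1.63 ± 0.23), and the transporter OPT3 (AT4G16370, -1.02 ± 0.20).

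In chlorophyll synthesis 5 of 24 members were lower and 0 higher (5 and 0 adjusted over the list alone; adjusted p = 0.033, or 0.6 with an estimated correlation). An example was the synthesis gene HEMC (-0.54 ± 0.12). Of the clock genes 9 of 22 members were higher and 6 lower (11 and 7 adjusted over the list alone; adjusted p = 0.057). PRR9 was higher (2.12 ± 0.18) and LUX (AT3G46640) lower (-1.21 ± 0.10), and the list gave adjusted p = 0.019 without the 3 libraries. Of the photosystem genes 2 of 44 members were lower and 0 higher (0 and 0 adjusted over the list alone; adjusted p = 0.28), and adjusted p = 0.00018 without the 3 libraries. Of the root regulators 6 of 32 members were higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.41). The gibberellin synthesis gene GA20OX2 (AT5G51810) was higher (2.03 ± 0.19) and GA3OX2 (-1.70 ± 0.24) lower. Among called genes of at least 5 CPM with no overlap rises were led by AT2G19660 (5.54 ± 0.59), AT5G37950 (5.09 ± 0.51), TIP2;3 (4.52 ± 0.38), SAUR16 (4.48 ± 0.42) and ASN1 (3.98 ± 0.47), AT2G19660 being at 8.26 without the 3 libraries. ASN1 (AT3G47340) is the asparagine synthetase of dark and starved tissue, and TIP2;3 a water channel of the vacuole. Falls were led by AT2G22590 (-3.84 ± 0.39), CHS (-3.45 ± 0.29), FLS1 (-3.30 ± 0.21), TT7 (-2.84 ± 0.21) and AT3G20380 (-2.75 ± 0.36). The genotypes differed in 4321 genes, 2193 up and 2128 down in hy1, 1160 by at least 2-fold (812 up and 348 down), and in 7244 without the 3 libraries. The count was 2549 without hy1 24 h replicate 1 and 2728 without hy1 24 h replicate 2.

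The genotype by light interaction at 12 h, the light response of hy1 minus that of WT, asks which genes changed differently in the mutant. A difference at 0 h enters it with reversed sign. Most auxin response and shade genes had a positive interaction. Of the auxin response genes 28 of 45 members had a positive and 1 a negative interaction (31 and 1 adjusted over the list alone, with adjusted p = 5.6e-15), GH3.5 at 1.79 ± 0.17, adjusted p = 2.5e-05 and GH3.3 at 2.80 ± 0.31. Of the PIF and shade genes 10 of 16 members had a positive and 1 a negative interaction (13 and 2 adjusted over the list alone, with adjusted p = 4e-07). HAT3 had an interaction of 1.95 ± 0.21. Of the flavonoid genes 0 of 23 members had a positive and 8 a negative interaction (0 and 9 adjusted over the list alone, with adjusted p = 0.0017, or 0.25 with an estimated correlation). CHIL had an interaction of -2.20 ± 0.30. The interaction of CHS itself, chosen after its values were seen, did not pass (-0.28 ± 0.72). Of the photosystem genes 21 of 44 members had a positive and 0 a negative interaction (31 and 0 adjusted over the list alone, with adjusted p = 2.1e-11, or 0.32 with an estimated correlation). LHCB2.1 (AT2G05100) had an interaction of 3.12 ± 0.60, and these genes lay lower in the 3 WT libraries that stood apart. Of the clock genes 5 of 22 members had a positive and 9 a negative interaction (5 and 10 adjusted over the list alone, with adjusted p = 0.015, or 0.31 with an estimated correlation). LHY had an interaction of 3.07 ± 0.30, GI of -2.89 ± 0.26 and PRR3 of -1.48 ± 0.13. In wall loosening 9 of 21 members had a positive and 2 a negative interaction (11 and 3 adjusted over the list alone, with adjusted p = 0.0018, or 0.23 with an estimated correlation). An example was XTH16 (3.92 ± 0.51), at 4.98 without the 3 libraries.

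Of the jasmonate genes 1 of 21 members had a positive and 6 a negative interaction (1 and 10 adjusted over the list alone, with adjusted p = 0.0032, or 0.31 with an estimated correlation). An example was JAZ1 (-3.28 ± 0.67). These genes lay higher in the 3 WT libraries, and without them JAZ1 was at -1.87 and the list gave adjusted p = 0.022. Of the ethylene genes 4 of 17 members had a positive and 7 a negative interaction (4 and 9 adjusted over the list alone, with adjusted p = 0.021, or 0.31 with an estimated correlation), the median (-0.537) and the test pointing down and the mean (0.204) up. EBF1 was at -1.40 ± 0.12. In light signalling 3 of 38 members had a positive and 10 a negative interaction (4 and 15 adjusted over the list alone, with adjusted p = 0.016, or 0.32 with an estimated correlation). BBX24 (AT1G06040) had an interaction of -1.17 ± 0.13. Of the root regulators 2 of 32 members had a positive and 5 a negative interaction (2 and 9 adjusted over the list alone, with adjusted p = 0.031, or 0.34 with an estimated correlation). WOX11 had an interaction of -4.64 ± 0.78. Of the secondary wall genes 0 of 13 members had a positive and 4 a negative interaction (1 and 4 adjusted over the list alone, with adjusted p = 0.022, or 0.34 with an estimated correlation). These last 3 calls were absent without the 3 libraries (adjusted p = 0.13, 0.55 and 0.068). Of the stomatal markers 1 of 6 members had a positive and 0 a negative interaction (4 and 0 adjusted over the list alone, with adjusted p = 0.028, or 0.31 with an estimated correlation), the member being TMM (AT1G80080), a receptor of stomatal patterning (4.02 ± 0.90). Among called genes with a mean of at least 5 CPM positive interactions were led by LHCB1.2 (6.53 ± 1.23), LHCB1.1 (5.70 ± 1.12), AT1G06360 (5.38 ± 0.67), LHCB2.2 (4.75 ± 0.76) and AT2G19660 (4.74 ± 0.49). Negative ones were led by AT1G19900 (-4.64 ± 0.62), DREB2A (-4.55 ± 0.52), CYP94B3 (-4.49 ± 0.62), AT2G34610 (-4.24 ± 0.64) and AT4G34380 (-4.18 ± 0.43), the first of which was not called without the 3 libraries (adjusted p = 0.075), and AT2G34610 was at -3.03 without them. The LHCB genes named are near-identical paralogs, whose reads cannot always be told apart. In all 2835 genes passed, 1411 positive and 1424 negative, 1584 of them at least 2-fold (920 positive and 664 negative), and 2678 without the 3 libraries, 1741 of them shared. The count was 8626 without WT 12 h replicate 1, 1766 without WT 12 h replicate 3, 1818 and 1699 without WT 0 h replicates 1 and 2, 1661 without hy1 0 h replicate 2 and 1691 without hy1 12 h replicate 3. Upper-quartile scaling moved the median interaction of all genes from 0.019 to 0.125, so that values here are relative to TMM scaling.

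The interaction at 24 h asks the same after a day. Most auxin response, shade and wall loosening genes had a positive interaction. Of the auxin response genes 31 of 45 members had a positive and 1 a negative interaction (32 and 1 adjusted over the list alone, with adjusted p = 3.8e-24), GH3.5 at 2.33 ± 0.17, adjusted p = 2e-06 and GH3.3 at 3.61 ± 0.31. The negative one was IAA28 (AT5G25890, -1.85 ± 0.16). Of the PIF and shade genes 10 of 16 members had a positive and 0 a negative interaction (14 and 1 adjusted over the list alone, with adjusted p = 3.6e-12). Examples were HAT2 (1.67 ± 0.13) and IAA29 (3.71 ± 0.51). In wall loosening 12 of 21 members had a positive and 1 a negative interaction (15 and 1 adjusted over the list alone, with adjusted p = 3.9e-10). EXPA8 had an interaction of 4.64 ± 0.63 and XTH17 of 1.86 ± 0.27. Of the iron genes 0 of 8 members had a positive and 3 a negative interaction (0 and 5 adjusted over the list alone, with adjusted p = 3.3e-05). NAS4 had an interaction of -1.96 ± 0.33. Of the flavonoid genes 1 of 23 members had a positive and 6 a negative interaction (1 and 9 adjusted over the list alone, with adjusted p = 0.0018, or 0.2 with an estimated correlation). The activator MYB12 (AT2G47460) had an interaction of -2.59 ± 0.33. Of the photosystem genes 2 of 44 members had a positive and 0 a negative interaction (1 and 0 adjusted over the list alone, with adjusted p = 2e-06, or 0.43 with an estimated correlation). LHCB2.1 had an interaction of 3.03 ± 0.60. These genes lay lower in WT 24 h replicate 3, and without the 3 libraries the list gave adjusted p = 0.00016.

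Of the jasmonate genes 1 of 21 members had a positive and 6 a negative interaction (1 and 8 adjusted over the list alone, with adjusted p = 0.0035, or 0.21 with an estimated correlation). VSP1 had an interaction of -1.89 ± 0.34, and without the 3 libraries, where these genes lay higher, the list gave adjusted p = 0.027. Of the ethylene genes 4 of 17 members had a positive and 10 a negative interaction (4 and 10 adjusted over the list alone, with adjusted p = 0.012, or 0.21 with an estimated correlation), the median (-0.806) and the test again down and the mean (0.67) up. In auxin synthesis and transport 3 of 28 members had a positive and 1 a negative interaction (6 and 1 adjusted over the list alone, with adjusted p = 0.012, or 0.2 with an estimated correlation). ABCB19 (AT3G28860), an auxin exporter, had an interaction of 1.34 ± 0.24. In the gibberellin list 5 of 16 members had a positive and 3 a negative interaction (5 and 3 adjusted over the list alone, with adjusted p = 0.034, or 0.18 with an estimated correlation), and adjusted p = 0.088 without the 3 libraries, with GA20OX2 at 2.38 ± 0.26. Of the endodermis markers 3 of 10 members had a positive and 0 a negative interaction (5 and 0 adjusted over the list alone, with adjusted p = 0.0058, or 0.2 with an estimated correlation). Of the stomatal markers 1 of 6 members had a positive and 0 a negative interaction (4 and 0 adjusted over the list alone, with adjusted p = 0.015, or 0.21 with an estimated correlation). Of the root regulators 2 of 32 members had a positive and 3 a negative interaction (2 and 3 adjusted over the list alone, with adjusted p = 0.35), WOX11 at -4.81 ± 0.79. Among called genes of at least 5 CPM positive interactions were led by AT5G37950 (6.93 ± 0.60), AT2G19660 (6.69 ± 0.64), DGR1 (5.45 ± 0.42), RGF9 (5.02 ± 0.44) and AT4G28780 (5.02 ± 0.43), AT2G19660 being at 9.41 without the 3 libraries. Negative ones among them were led by CML38 (-4.19 ± 0.71), AT1G49570 (-4.05 ± 0.78), AT4G34380 (-3.98 ± 0.46), CYP94B3 (-3.96 ± 0.61) and DREB2A (-3.86 ± 0.52). DREB2A (AT5G05410) is a factor of drought and heat response, and RGF9 a root growth peptide. In all 1816 genes passed, 1085 positive and 731 negative, 1142 of them at least 2-fold (738 positive and 404 negative), and 3568 without the 3 libraries, 1784 of them shared.

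Light responses were compared across all 20955 genes, which are not independent replicates. Log2 changes of hy1 and WT correlated at Pearson r = 0.72 at 12 h (Spearman rho = 0.641) and 0.756 at 24 h (0.725). Slopes of hy1 on WT, which spread in the WT values lowers, were 0.662 and 0.672. Of 6573 genes called in both genotypes at 12 h 6378 changed in the same direction (6324 of 6466 at 24 h). At these times 4667 and 3535 were called in WT alone, 2690 and 2018 in hy1 alone. CHS, FLS1, RCA and GUN5 rose in both genotypes at both times, and GH3.5, IAA6, XTH17 and YUC9 fell.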

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

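The tests chosen only after the results were seen were the length and GC correction of the 3 libraries, the tests of the touch and wound genes, the clock tests other than that of phase, the auxin starting level, the groups for phosphate, dark and sugar starvation, touch and abscisic acid, and the counts of splits.

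At 12 h 2835 genes had an interaction and at 24 h 1816. Lists called at 12 h were photosystem (adjusted p = 2.1e-11), auxin response (5.6e-15), PIF and shade (4e-07), flavonoid (0.0017), wall loosening (0.0018), jasmonate (0.0032), clock (0.015), light signalling (0.016), ethylene (0.021), secondary wall (0.022), stomatal (0.028) and root regulator (0.031) genes. With an estimated correlation 2 of the 23 lists were called at 12 h, auxin response (0.0077) and PIF and shade (0.0051). Of the groups drawn up later, those for touch (3.7e-06) and abscisic acid (0.0016) were called too, though not with an estimated correlation (0.17 and 0.15). Lists called at 24 h were auxin response (adjusted p = 3.8e-24), PIF and shade (3.6e-12), wall loosening (3.9e-10), photosystem (2e-06), iron (3.3e-05), flavonoid (0.0018), jasmonate (0.0035), endodermis (0.0058), ethylene (0.012), auxin synthesis (0.012), stomatal (0.015) and gibberellin (0.034) genes, and later groups for touch (6.2e-05) and phosphate (0.0038), both of these later groups not called with an estimated correlation (0.3 and 0.056). At 24 h 4 of the 23 lists were called with an estimated correlation, auxin response (0.0012), PIF and shade (0.00043), wall loosening (0.0043) and iron (0.0067). The log2 interactions of named genes at 12 h were LHY 3.07, BBX24 -1.17, AT1G06360 5.38, JAZ1 -3.28, AT1G19900 -4.64, GI -2.89, LHCB1.2 6.53, LHCB1.1 5.70, TMM 4.02, LHCB2.2 4.75, LHCB2.1 3.12, AT2G19660 4.74, GH3.3 2.80, EBF1 -1.40, AT2G34610 -4.24, WOX11 -4.64, XTH16 3.92, CYP94B3 -4.49, HAT3 1.95, GH3.5 1.79, AT4G34380 -4.18, CHIL -2.20, DREB2A -4.55 and PRR3 -1.48. At 24 h they were AT1G49570 -4.05, NAS4 -1.96, XTH17 1.86, CML38 -4.19, DGR1 5.45, LHCB2.1 3.03, AT2G19660 6.69, GH3.3 3.61, HY1 -0.66, EXPA8 4.64, MYB12 -2.59, WOX11 -4.81, ABCB19 1.34, CYP94B3 -3.96, GH3.5 2.33, AT4G28780 5.02, IAA29 3.71, AT4G34380 -3.98, DREB2A -3.86, VSP1 -1.89, IAA28 -1.85, AT5G37950 6.93, HAT2 1.67, GA20OX2 2.38 and RGF9 5.02.

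Splits of the libraries into groups of the same sizes were counted for every comparison. For the interactions, 3 of 100 splits drawn from the libraries gave at least the real 2835 genes at 12 h (highest other 3634), and 2 of 100 gave at least the real 1816 at 24 h (highest other 6827), the real split included. Splits that mix the genotypes add the genotype difference to the spread within groups, so that these low shares do not exclude interactions called by chance. At 24 h the split with more genes set all hy1 0 h and WT 24 h libraries against the rest, which turns the interaction into the sum of the genotype differences at 0 h and 24 h, so that the structure of the samples it points to is genotype. The pair with more genes at 12 h kept the genotypes whole at 0 h and mixed them at 12 h, and what raised their counts was not tested. The 10 splits of 6 libraries are too few for a share under 0.05. In WT at 24 h against 12 h 2 of the 10 splits gave at least the real 1902, and the highest other, 10748, set the 3 libraries that stood apart against the rest, several times the real count, which points to that structure of the samples. In the other 8 comparisons only the real split, 1 of 10, reached its count: 11240, 10001, 9263, 8484, 1025, 6853 and 4321 with 0 as the highest other, and 5154 for hy1 against WT at 0 h with 1. The other splits there mix the 2 groups compared, which adds the difference between them to the spread within groups. Their low counts were thus favoured and do not exclude calls by chance.

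The 3 WT libraries named above stood apart from their groups. An exchange of time labels was argued against, since on the genes called between 24 h and 12 h in hy1 the lowest WT 24 h library scored 0.643 log2 above the highest WT 12 h library. Gene length and GC content as the whole cause were argued against too: the difference of the 3 libraries from the others correlated across genes between 12 h and 24 h at r = 0.737 before and 0.716 after each library was corrected for both. Tissue of another kind cannot be told apart from the groups' own tissue, because the largest of the 4 lists' medians, that of seed reserve markers, was -0.528, neither above 1 nor under 0.5 in size. A difference in library preparation or in the part of the hypocotyl taken stays open, and apart from tissue of another kind no biological explanation was tested.

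Rapid touch and wound genes were higher in hy1 at 0 h, a call lost with an estimated correlation (adjusted p = 0.091). A single hy1 library as the source could not be excluded, since the median log2 CPM of the list was above all WT 0 h libraries in 2 of 3 hy1 libraries (3.66, 4.21 and 4.88, against 3.74, 2.99 and 3.06 in WT). A genotype effect of equal size in dark and light cannot be excluded: 10 members had a negative interaction at 12 h, 7 without the 3 libraries, but choosing genes that differed between genotypes can favour that sign. Handling or harvest that differed between the dark groups cannot be told apart from the genotype in darkness, as the labels give no harvest apart from the group, and the median difference at 24 h was 0.016. A genotype effect seen in darkness alone stays open.

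Clock genes differed between hy1 and WT at 12 h. The 3 WT libraries as the source were argued against, as 14 of the 18 called clock genes were called in the same direction without them. A later harvest of the hy1 plants at 12 h alone could not be decided on. At 24 h 15 of 22 clock genes differed, but these differences could have a cause of their own. Clock genes also differed at 0 h, as given above. A later clock phase in the hy1 12 h libraries may account for the pattern: across the 22 clock genes, which are not independent replicates, hy1 minus WT at 12 h followed the WT change from 12 h to 24 h, with different WT 12 h libraries on each side, at Pearson r = 0.9 and Spearman rho = 0.82 (two-sided permutation p = 1e-05, the smallest that 1e+05 resamples can give), and at r = 0.823 and rho = 0.741 with those libraries exchanged. A genotype effect on the clock and a later harvest of hy1, at 12 h alone or at both times, stay open.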

How the results depend on the processing

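The 3 libraries left out, the indicator term and the length and GC correction were chosen after the data were examined. Gene counts stayed within 1.5 times those given in 196 of 254 alternatives over the 11 comparisons. Naming favoured clear and so stable changes: 4761 of 4780 values of named genes kept direction and call, 19 lost the call and none reversed. Of 1012 list tests 900 stayed the same (lists called in neither fit included), 21 gained and 91 lost the call, and none reversed. The estimated correlation, with 253 of these tests, accounted for 78 of the losses. In the order WT 12 h, WT 24 h, hy1 12 h and hy1 24 h against 0 h, a fold of at least 2 left 5002, 4444, 3883 and 3548 genes. For WT at 24 h against 12 h the DESeq2 Wald test gave 2913, the groups alone 111, the 3 libraries left out 964, adjusted p under 0.01 766, a fold of 2 698, and leaving out 1 library 935 to 8279. For hy1 at 24 h against 12 h the same settings gave 1693, 3117, 3500, 471, 384 and 522 to 663, and the indicator term 2976. For hy1 against WT at 0 h the groups alone gave 9154, the 3 libraries left out 9750, the term 9078, adjusted p under 0.01 2884, a fold of 2 1763 and 1 library left out 3424 to 4323. At 12 h the groups alone gave 1496, the 3 libraries left out 4085, adjusted p under 0.01 3268, a fold of 2 2062 and 1 library left out 4057 to 11090. At 24 h the 3 libraries left out gave 7244, the term 7193, adjusted p under 0.01 2025, a fold of 2 1160 and 1 library left out 2549 to 3615. For the interaction at 12 h adjusted p under 0.01 gave 937, a fold of 2 1584 and 1 library left out 1661 to 8626. For that at 24 h the 3 libraries left out gave 3568, the term 3357, adjusted p under 0.01 836 and a fold of 2 1142. Stricter thresholds call fewer genes by construction, and for the other settings the cause was not tested. With an estimated correlation the lists called over the 11 comparisons, in the order given, fell to 5, 7, 3, 2, 2, 2, 0, 2, 3, 2 and 4 of 23. For hy1 against WT at 24 h the replicate block and the term each gave 11. HY1 at 0 h lost its call with no filter (log2 change -0.38, adjusted p = 0.06). It also did with any 1 of 6 libraries left out (-0.44 to -0.33). At 12 h it gained one under DESeq2 size factors (-0.35), the DESeq2 Wald test (-0.35), without organelle genes (-0.34), without the 3 libraries (-0.63), with the term (-0.58), with the length and GC correction (-0.44), and without WT 12 h replicate 3 or hy1 12 h replicate 1 (adjusted p = 0.03 and 0.042), the values with 1 library left out running from -0.44 to -0.17. The correlation across genes of the light responses moved by more than its jackknife error with no filter (0.495 at 12 h and 0.526 at 24 h), with the stricter filter at 24 h (0.795), without WT 12 h replicate 1 at 12 h (0.648) and without WT 24 h replicate 1 at 24 h (0.715). The other 22 fits with 1 library left out (up to 0.712 and 0.756) moved it by less. Simulated data had the depth of these libraries and 1 spread per gene, fitted over all 18. The parts of depth and of spread in the changes missed were not tested.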

Other observations

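All tests of the 4 gene groups described here and of the explanation for the auxin response genes were chosen after the results were seen. The 4 groups were drawn up from genes that differed between genotypes, so their direction is not independent evidence.

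Of genes induced by phosphate starvation more were higher than lower in hy1 at each time. At 0 h 6 of 13 members were higher and 1 lower (adjusted p = 0.0043), at 12 h 7 of 13 members were higher and 0 lower (adjusted p = 0.00048) and at 24 h 10 of 13 members were higher and 0 lower (adjusted p = 2.3e-08). AT4 (AT5G03545), a non-coding RNA of phosphate starvation, differed by 1.84 ± 0.24 at 0 h, 3.54 ± 0.26 at 12 h and 2.49 ± 0.24 at 24 h, and the acid phosphatase PAP17 (AT3G17790) by 1.26 ± 0.14, 1.67 ± 0.14 and 1.81 ± 0.14. In the interaction at 24 h 2 of 13 members had a positive and 0 a negative interaction (adjusted p = 0.0038, or 0.056 with an estimated correlation). Genes induced by darkness and sugar starvation, many of which break down amino acids and sugars, were higher too. At 0 h 14 of 15 members were higher and 0 lower (adjusted p = 3.3e-11). At 12 h 12 of 15 members were higher and 0 lower (adjusted p = 1.2e-06, or 0.073 with an estimated correlation), and at 24 h 13 of 15 members were higher and 0 lower (adjusted p = 4.1e-12). IVD (AT3G45300), of leucine breakdown, differed by 1.62 ± 0.20, 1.23 ± 0.20 and 1.72 ± 0.20 at the 3 times.

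Rapid touch and wound genes were higher in hy1 in the dark, where 11 of 16 members were higher and 0 lower (adjusted p = 5.1e-07, or 0.091 with an estimated correlation). Examples were CBF1 (AT4G25490, 3.41 ± 0.55), a cold response factor, and the zinc finger gene ZAT12 (AT5G59820, 1.79 ± 0.29). At 12 h 0 of 16 members were higher and 3 lower (adjusted p = 0.36), and at 24 h 1 of 16 members were higher and 2 lower (adjusted p = 0.99). In the interaction at 12 h 0 of 16 members had a positive and 10 a negative interaction (adjusted p = 3.7e-06, or 0.17 with an estimated correlation), and at 24 h 0 of 16 members had a positive and 5 a negative interaction (adjusted p = 6.2e-05, or 0.3 with an estimated correlation). In hy1 alone 15 of 16 members fell and 0 rose (adjusted p = 6.2e-08, or 0.15 with an estimated correlation) from 0 h to 12 h. Of the abscisic acid genes 6 of 13 members were higher and 0 lower (adjusted p = 9e-04) at 0 h, 2 of 13 members were higher and 3 lower (adjusted p = 0.69) at 12 h and 6 of 13 members were higher and 1 lower (adjusted p = 0.005, or 0.091 with an estimated correlation) at 24 h. NCED3 (AT3G14440), of abscisic acid synthesis, was higher at 0 h (1.65 ± 0.25), and in the interaction at 12 h 0 of 13 members had a positive and 5 a negative interaction (adjusted p = 0.0016, or 0.15 with an estimated correlation).

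One hypothesis on the auxin response genes was tested, that their smaller fall in hy1 could come as a whole from their lower starting level in the dark. Both genotypes would then end at the same level, with a median near 0 at 24 h. The median of the list in hy1 against WT at 24 h was 0.703, with 24 of 45 members higher and 1 lower, which argues against the starting level as the whole cause. A part of the smaller fall from that source stays open, as does the reason for the higher level in light.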
